A study of Mus musculus with 8 samples.

How the data were processed

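RNA from the cerebral cortex of C57BL/6 mice at postnatal day 0 was measured on a custom Agilent array that tiles both strands of a span of chromosome 7 around Ube3a. Per the labels' protocols, 15 µg of total RNA, or 750 ng of polyA RNA purified from 30 µg of total RNA on oligo(dT) beads, was made into Cy5-labelled first-strand cDNA with random hexamers. First-strand cDNA keeps the strand of its RNA, so each strand of the locus was read by its own probes. The 8 arrays lay on 1 slide and share 1 scan, so neither slide nor scan could be fitted as a batch. Per the labels, the sample is in the red channel. The green channel held no labelled sample and its median intensity was 27 on all arrays.

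The deposited scanner files hold intensity values of each spot on a linear scale, 1 array per file, with no normalization between arrays. Per the file headers, they were made with Agilent Feature Extraction 10.7.3.1 for an array design on genome build mm9 (NCBI build 37), whereas the submitters' processing notes name version 10.9. The labels point to the median pixel intensity of the red channel as the value of a spot, and that column was used. A series matrix deposited by the authors was used as an alternative. It holds the same red intensity of 18408 features multiplied by 1 factor per array, which ranged from 0.859 to 1.024 on the total RNA arrays and was 1.966 and 1.984 on the polyA arrays. Its scale was found from the values, and how the factors were chosen is not given in the sources used here. The median of its columns was 104 for the maternal deletion, 75.4 for the paternal deletion, 89 and 86 for the wild types, 76.9 and 105.8 for the double deletions, and 78.7 and 77.4 for polyA RNA.

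Each array has 57933 spots that are not controls. They hold 53834 distinct probes, of which 50496 lie in the tiled locus and 3338 outside it. Red intensities were background-corrected with the normexp method (offset 50) in limma 3.58.1 under R 4.3.3, put on the log2 scale and scaled by subtracting the array's 75th percentile. Control spots and spots with an outlier mark of the scanner software were left out after the correction, and spots of the same probe were averaged. A probe was tested if it was well above background on every array of at least 1 group, which left 49384 probes with values on all total RNA arrays and 43871 for the polyA comparison.

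Samples were grouped from the labels alone. The total RNA samples comprise 1 maternal deletion, 1 paternal deletion, 2 wild types and 2 double deletions, and both polyA samples come from the RNA of the wild types. The 2 double deletions carry different deletions of the paternal Snrpn promoter, designated 0.9 and 4.8 in the labels. The title and the genotype label of each sample name opposite ones, so the samples are called replicate 1 and replicate 2 and no value is assigned to either deletion. Nothing says how many animals stand behind a sample, so p-values measure only the spread between these samples.

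The following was fixed before the data were examined. Probes and transcription units were to be compared with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) on values scaled to the 75th percentile of all probes. The 6 total RNA samples formed 4 groups that share 1 estimate of the spread, with the double deletions as 1 group. The 4 wild-type samples formed a separate fit for polyA RNA. Transcription units were meant to be exons, introns and antisense strands of annotated genes. No annotation of build mm9 was used here, so 10-kb bins of each strand with at least 3 tested probes took their place, 356 in all. For the same reason the lists of genes and cell type markers, and the rule that named genes, could not be applied by gene. The rule's other parts name both strands of Ube3a first and the bins over the span from Snrpn to Ube3a. They also name the 10 bins with the largest change outside it among those past the threshold. That last part was not applied as fixed: its bins passed the threshold on the outside-locus scale with separate double-deletion samples, a fit chosen later (below). Under the planned fit it would have named none for the maternal deletion or for the double against the maternal deletion.

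Other choices followed the data. The planned scale depends on the strong signal inside the locus: compared with a scale on the 75th percentile of probes outside the locus, it adds 0.01 to the log2 change of the maternal deletion, 1.12 to that of the paternal deletion, 0.38 to that of the double deletion, 0.37 to the double against the maternal deletion and 1.26 to polyA against total RNA. The outside-locus scale had been listed as an alternative beforehand. It was chosen for the regional changes between genotypes after seeing this shift, and the double-deletion samples were taken there as separate groups after they were seen to differ. The mean of both is then compared with the other groups, and the spread rests on the wild-type pair alone, with 1 residual degree of freedom. Samples without a replicate are assumed to vary like that pair. The planned grouping for probes and transcription units, with the double deletions pooled, was tried on the regions as an alternative. Its adjusted p-values are printed beside the calls, and standard errors of the double deletion are from that fit. Unless given as pooled, standard errors of the single deletions are from the fit with separate samples and rest on the wild-type pair alone. They are therefore not comparable with those of the double deletion.

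Regions were drawn from the data. Change points of the plus strand were found by least squares on the change from wild type in windows around the ends of the deletion. The Ube3a block was found by least squares on the plus-strand wild-type signal, and 5 plateaus of the minus strand by segmenting wild-type bin medians. The number of plateaus was set and not estimated from the data. The value of a region is the mean over its tested probes. As the change points come from the arrays that are then tested, p-values of the regions that end there are not independent of the borders. The spread of the 20 combinations of region and strand was moderated in limma together with that of the bins, and p-values were adjusted over the 20. Moderation over the 20 alone was run first and gave adjusted p-values down to 2.7e-23, which 1 residual degree of freedom does not warrant, and was replaced. For polyA RNA the planned scale and groups were kept. Its fit of bins and regions estimated an infinite prior, so its p-values are not meaningful for single regions, and p-values with the replicate number as a block are given.

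Probe positions and strands are those of the files on mm9, and a probe whose coordinates are written end first was taken as minus strand. Gene names of regions rest on the study's labels and on the order of neighbouring genes in a RefSeq table of assembly GRCm38.p6, whose coordinates were not used. In that table Atp10a, Ube3a, the snoRNA clusters with Snhg14, Ipw and Snord116 copies, Snord64 and Snrpn with Snurf follow one another. Plateaus were not assigned to single genes.

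The wild-type and polyA samples with the same number share their RNA, which pairs them. Across 43871 probes, the difference between replicates 1 and 2 in total RNA correlated with that in polyA RNA at r = 0.19, and probes are not independent replicates. The median absolute log2 difference between replicates was 0.11 for wild-type total RNA, 0.08 for polyA RNA and 0.24 for the double deletion.

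The procedures were tested on simulated data. For the maternal deletion with separate double-deletion samples, 95% of probes raised by 2 on the log2 scale and 2.5% of those raised by 1 were recovered among 47007 probes, with 7 false calls. Of 356 bins, 90% of those raised by 0.5 and 100% of those raised by 1 were recovered, with 1 false call. With the planned groups, 90% of bins raised by 0.5 were recovered for the paternal deletion, with 7 false calls. The simulated double deletions differed only by noise like that of the wild-type pair. The measured ones differed by more, so this rate does not carry over to the planned groups. For polyA RNA, 82.5% of probes raised by 1 were recovered, with 13 false calls. In 100 of 100 draws the change point lay within 10 probes of the simulated one. Alternatives covered the background correction, the offset, the scale, the filter on dim probes, the series matrix, the samples in the fit, each replicate left out, the median over probes, and, for polyA RNA, the replicate block.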

Results

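The study measured RNA from both strands of a 1810-kb span of mouse chromosome 7 (positions 65890585 to 67700765, mm9) that holds Ube3a, an E3 ubiquitin ligase gene expressed mainly from the maternal allele in neurons, and the domain up to Snrpn. Ube3a lies on the plus strand. Its antisense RNA, Ube3a-ATS, belongs to a long minus-strand transcript that begins at Snrpn on the paternal allele. The 8 samples form 5 groups: a mouse line deleted from Snrpn to Ube3a on the maternal chromosome (n = 1), the same deletion on the paternal chromosome (n = 1), wild type (n = 2), the maternal deletion combined with a deletion of the paternal Snrpn promoter, called the double deletion here (n = 2), and polyA RNA of the same wild types (n = 2). The single deletions have no replicates. The 2 double deletions carry different deletions of the paternal Snrpn promoter, so neither promoter deletion has a replicate. Their SD and pooled spread hold that difference together with sample noise. Median red intensity was 98 to 161 on the 6 total RNA arrays over a local background of 36 to 38, and 45 and 44 on the polyA arrays over 34. Between 81.1% and 88.4% of spots were well above background with total RNA, and 61.4% and 56.6% with polyA RNA. The number of arrays limits the precision. Regional values are mean log2 signals relative to the 75th percentile of probes outside the locus on the same array, unless stated otherwise.

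In wild-type cortex a plus-strand block over Ube3a was drawn from 66483532 to 66566852. The part nearer its promoter, called the 5′ part (66483532 to 66526900), had a mean of 1.12 ± 0.04 (SD, n = 2), and the 3′ part (66526901 to 66566852) had 1.78 ± 0.02 (SD, n = 2). On the minus strand, the signal between Ube3a and Snrpn was cut into 5 plateaus, a number that was set and not estimated. The 270-kb plateau 2 (66600001 to 66870000) had a mean of 5.61 ± 0.14 (SD, n = 2), and plateau 4 (66930001 to 67060000) had 5.59 ± 0.02 (SD, n = 2). Plateau 5 (67060001 to 67140000), at the Snrpn end, had 3.20 ± 0.08 (SD, n = 2), plateau 3 (66870001 to 66930000) had 2.77 ± 0.04 (SD, n = 2) and plateau 1 (66570001 to 66600000), at the Ube3a end, had 1.71 ± 0.01 (SD, n = 2). Minus-strand signal went on through Ube3a, with 1.76 ± 0.04 (SD, n = 2) opposite the 3′ part and 1.06 ± 0.06 (SD, n = 2) opposite the 5′ part. By these means the Ube3a block did not stand above its lower side on either strand. The 100 kb below it, called the taper, had 2.24 on the plus and 2.05 on the minus strand. The lower flank beyond (65890585 to 66383531) had 1.32 and 1.38. Past the other end of the block, the plus strand had 0.62 opposite plateau 1. The upper flank (67147710 to 67700765) had 0.74 on the plus and 1.47 on the minus strand. Ube3a-ATS is the minus-strand RNA opposite Ube3a.

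**Figure D1:**
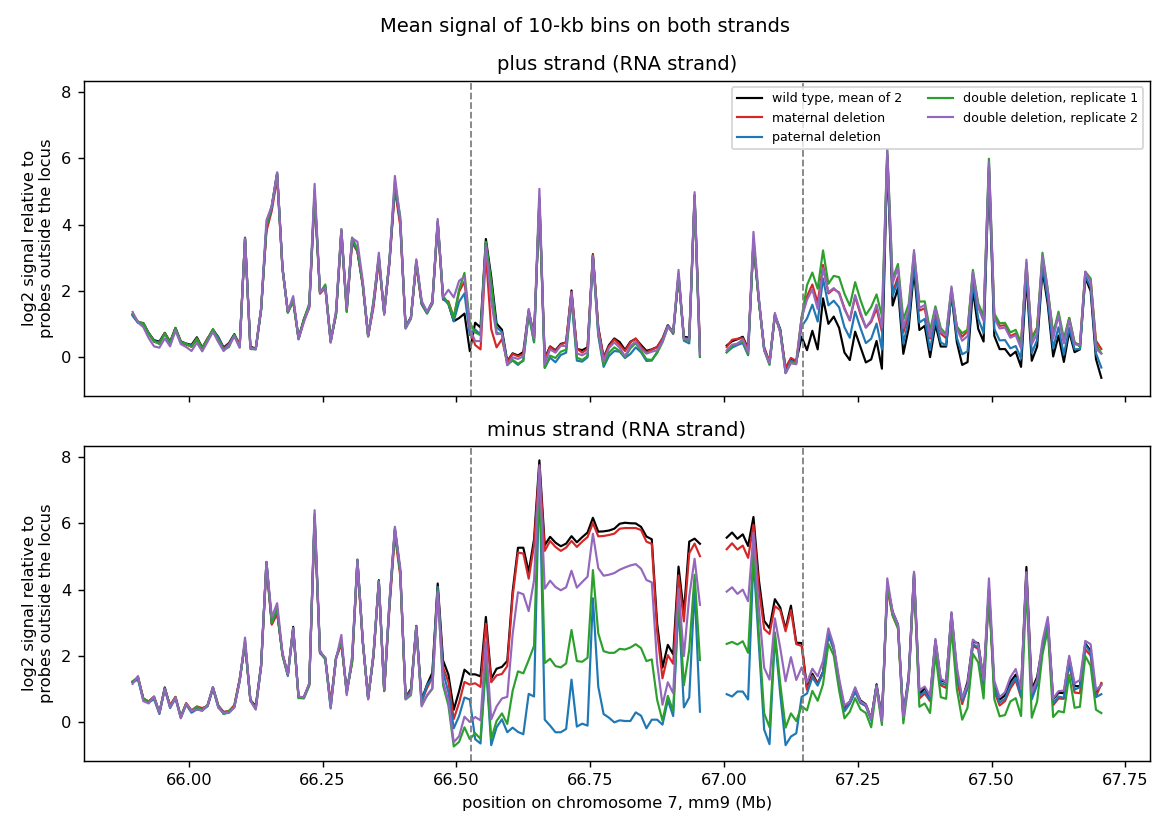
Mean log2 signal of 10-kb bins, relative to probes outside the locus, against position on chromosome 7 (mm9) for the plus strand (top) and the minus strand (bottom), with the mean of both wild types, each single deletion and each double-deletion replicate as lines. Dashed lines mark the change points near 66.53 and 67.15 Mb, between which the wild-type minus strand reached 5.61 over plateau 2 and the paternal deletion 0.51.

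The maternal deletion asks which RNA of the locus comes from the maternal chromosome. Plus-strand RNA over the deleted 3′ part of Ube3a fell by 0.82 on the log2 scale, to 0.96 against 1.78 in wild type, a 1.76-fold decrease. Its SE was 0.04 from the wild-type pair alone, or 0.16 with the double deletions pooled as 1 group. Over the 5′ part, which the deletion spares, plus-strand RNA rose by 0.63 (SE 0.05, or 0.13 with pooling). Beyond the other end of the deletion, in the 553.1-kb upper flank (67147710 to 67700765), it rose by 0.70 (SE 0.04, or 0.11 with pooling). In the wild types 66.4% and 65.3% of the probes of this flank were well above background, and its change ran from 0.51 (quantile normalization) to 1.97 (background-subtracted signal) over the settings tried. Of the 7 minus-strand regions from Ube3a to Snrpn, 5 were called lower, by less than the plus strand: plateau 4 fell by 0.32, plateau 3 by 0.28 and plateau 1 by 0.19, and the strand fell by 0.24 opposite the 3′ part of Ube3a and by 0.31 opposite the 5′ part. Plateaus 2 and 5 differed by -0.15 each, which did not pass the test (adjusted p = 0.295 and 0.164). Bins outside the span from Ube3a to Snrpn were ranked here and below among those past the threshold in the fit with separate double-deletion samples. The 10 with the largest change all lay on the plus strand between 67150001 and 67300000 and rose by 1.05 to 1.62. The plus-strand change points lay between probes at 66526853 and 66526901 and between probes at 67147632 and 67147710, and the change from wild type stepped from 0.98 to -0.61 at the first and from 0.01 to 1.30 at the second.

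In limma, adjusted p was 0.000917 for the 3′ part and for the upper flank, 0.00166 for the 5′ part, and on the minus strand 0.0108 for plateau 4, 0.0156 for plateau 3, 0.026 for plateau 1, 0.0188 opposite the 3′ part and 0.0163 opposite the 5′ part. These set 1 sample against the spread of the wild-type pair. The borders at the change points were drawn on the same deletion arrays, so these p-values overstate the certainty. Besides pooling, the strand opposite the 3′ part lost its call with probes well above background as the scale (-0.10). It also lost it on those probes alone (-0.18) and with all 8 samples in the fit (-0.24). Minus-strand plateau 1 also lost its call under 4 settings besides pooling, with changes from -0.33 to -0.05, and plateau 3 under 1, at -0.14 (adjusted p = 0.0839, range 7.23e-11 to 0.88). With the double deletions pooled as 1 group, they became 0.0811 for the 3 plus-strand regions, 0.447 opposite the 5′ part and 0.88 for the other 4, so none of these calls outlasted pooling.

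The paternal deletion asks the same of the paternal chromosome. Minus-strand RNA fell in all 5 plateaus of the deleted span. It fell by 5.10 in plateau 2 (SE 0.09, or 1.08 with the double deletions pooled). The change there ran from -6.27 (background-subtracted signal) to -2.79 (catalogue probes) over the settings tried. Standard errors not marked as pooled rest on the wild-type pair alone. Within plateau 2, the bin from 66650001 to 66660000 changed by only -0.41, to 7.50 against 7.94 and 7.87 in the wild types. Minus-strand RNA fell by 4.09 (SE 0.04) in plateau 4, by 2.96 in plateau 5 (-5.07 to -1.70 over the settings), by 2.08 in plateau 3 (-3.89 to -0.82) and by 1.85 in plateau 1 (-3.95 to -0.58). Opposite the 3′ part of Ube3a it fell by 1.93 (SE 0.05) to -0.17, a level at which 51.8% of probes were well above background. The size of this decrease depends on the processing, with changes from -4.32 (background-subtracted signal) to -0.67 (scaled on probes well above background). Opposite the 5′ part, outside the deletion, it fell by 0.60 (SE 0.06) on this scale, and rose by 0.52 on the planned scale. Plus-strand RNA of the 3′ part had 1.60 against 1.78, and the sign of this difference of -0.18 (SE 0.04) turned under 4 other scalings, with 0.94 on the planned scale. The plus strand rose by 0.37 (SE 0.05, or 0.13 with pooling) over the 5′ part, with 0.29 to 1.63 over the settings tried. Over the upper flank it rose by 0.33 (SE 0.04, or 0.11 with pooling), with 0.26 to 1.60 over the settings tried. The plus-strand change points fell between the same probes as in the maternal deletion. On the minus strand, the lower change point lay between probes at 66526930 and 66526935, 77 bp away, and the change from wild type there stepped from -0.63 to -1.87. The 10 bins with the largest change outside the span lay on the plus strand between 67150001 and 67280000 and rose by 0.58 to 0.96. Minus-strand plateaus 1, 3 and 5 were called lower as well. With the double deletions pooled, plateau 5 lost its call, and plateaus 1 and 3 stayed just past the threshold.

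Adjusted p in limma was 9.29e-06 for plateau 2, 2.53e-06 for plateau 4, 1.04e-05 opposite the 3′ part, 0.0015 opposite the 5′ part, 0.0276 for the plus strand of the 3′ part, 0.00405 for that of the 5′ part and 0.00369 for the upper flank. With the double deletions pooled as 1 group they became 0.0615, 0.0497, 0.0497, 0.0672, 0.455, 0.126 and 0.126, so plateau 4 and the strand opposite the 3′ part stayed past the threshold and the others named here did not.

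**Figure D2:**
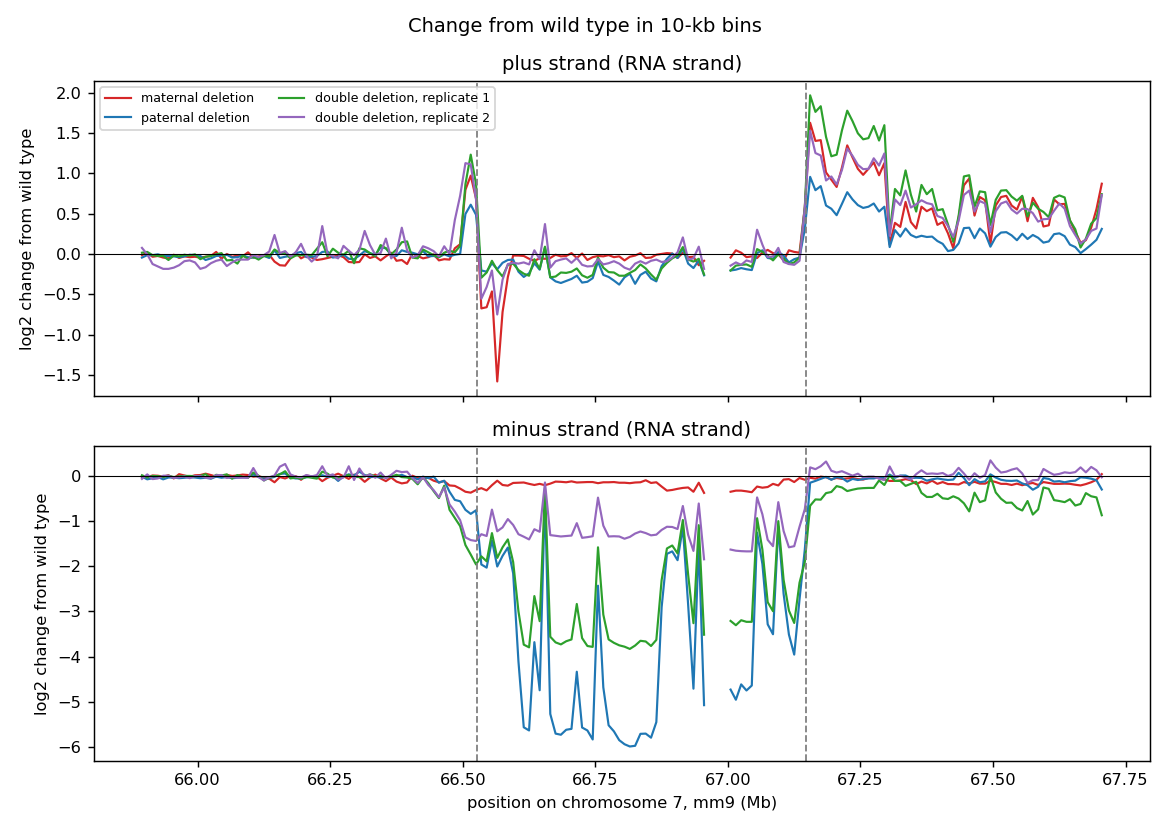
Log2 change from the mean of both wild types in 10-kb bins against position on chromosome 7 (mm9), for the plus strand (top) and the minus strand (bottom), with a line for each deletion array and dashed lines at the change points. Beyond the upper change point the plus strand averaged 0.70 above wild type in the maternal deletion, 0.33 in the paternal deletion, and 0.90 and 0.70 in the double-deletion replicates, all on the scale of probes outside the locus.

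The double deletion, which removes the paternal Snrpn promoter besides the maternal span, leads to depletion of Ube3a-ATS per the series description, and the comparison with wild type measures by how much each strand changed. Minus-strand RNA opposite the 3′ part of Ube3a fell by 1.49 (SE 0.23), with -1.76 in replicate 1 and -1.21 in replicate 2, and with changes from -2.50 to -0.67 over the settings tried. Opposite the 5′ part it fell by 1.34 (SE 0.11, -2.61 to -0.53 over the settings), with -1.47 and -1.22. In the taper below Ube3a it fell by 0.26 (SE 0.04, -0.67 to 0.55 over the settings), with -0.28 and -0.24. It also fell in plateau 1, by 1.36 (SE 0.24; -2.25 to -0.54 over the settings), and in plateau 3, by 1.44 (SE 0.26; -2.22 to -0.63). Both replicates were below wild type in plateaus 2 (-3.36 and -1.23), 4 (-2.82 and -1.45) and 5 (-2.52 and -1.28) too, where the mean differences of -2.29 (SE 0.88), -2.13 (SE 0.56) and -1.90 (SE 0.51) did not pass the test with the replicates as 1 group. Plus-strand RNA rose by 0.83 (SE 0.10) over the 5′ part (0.59 to 1.64 over the settings tried) and by 0.80 (SE 0.09) over the upper flank (0.68 to 2.08 over the settings tried), with 0.90 and 0.70 in the replicates. The 3′ part, deleted on the maternal chromosome, differed by -0.35 (SE 0.13) on the plus strand, with -0.20 and -0.50 in the replicates, which did not pass that test, and was 0.03 higher on the planned scale and 0.46 higher when scaled on probes well above background. The 10 bins with the largest change outside the span lay on the plus strand between 67150001 and 67300000 and rose by 1.25 to 1.74.

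With the replicates pooled as 1 group, adjusted p in limma was 0.0357 opposite the 3′ part and for plateaus 1 and 3, 0.027 opposite the 5′ part, 0.0286 for the plus strand of the 5′ part and of the upper flank, 0.135 for plateau 2, 0.0769 for plateaus 4 and 5 and 0.13 for the plus strand of the 3′ part. With the replicates as separate groups, whose own difference the spread then leaves out, it was 2.13e-05 opposite the 3′ part and for plateaus 1, 3 and 5, 3.13e-05 opposite the 5′ part and for plateau 2, 1.43e-05 for plateau 4, 9.05e-05 for the plus strand of the 5′ part, 6.27e-05 for the upper flank and 0.00127 for the plus strand of the 3′ part.

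Set against the maternal deletion alone, the double deletion asks what losing the paternal promoter does on the same maternal background. With 1 maternal-deletion sample and 2 double-deletion samples that differ, an effect of the promoter and a difference between samples cannot be told apart. Plus-strand RNA of the 3′ part of Ube3a, which lies on the paternal chromosome alone in both genotypes, differed by 0.47 (SE 0.16), with a mean of 1.43 ± 0.21 (SD, n = 2) against 0.96. Over the settings tried it ran from 0.32 (without replicate 1) to 1.14 (scaled on probes well above background). Replicate 1 had 1.58 and replicate 2 had 1.28, between the maternal deletion and wild type. Opposite it, the minus strand differed by -1.24 (SE 0.28), from -2.14 (background-subtracted signal) to -0.57 (scaled on probes well above background). Plateau 2 differed by -2.14 (SE 1.08), by -3.21 without replicate 2 and by -1.08 without replicate 1. The 5′ part differed by 0.20 (SE 0.13) on the plus strand, by 0.08 without replicate 2, and by -1.03 (SE 0.14) on the minus strand. The upper flank differed by 0.10 (SE 0.11) on the plus strand, with 0 to 0.77 over the settings tried. The 10 bins with the largest change outside the span were mixed, 6 on the plus strand and 4 on the minus strand, from -0.48 to 0.35.

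With the replicates pooled as 1 group, none of these 6 differences passed the test in limma, with adjusted p of 0.18 for both strands of the 3′ part, 0.284 for plateau 2, 0.365 and 0.103 for the plus and minus strands of the 5′ part and 0.561 for the upper flank. With the replicates as separate groups, set against 1 maternal-deletion sample and the spread of the wild-type pair, adjusted p was 0.00115 and 8.52e-05 for the plus and minus strands of the 3′ part, 9.96e-05 for plateau 2, 0.036 and 0.000187 for those of the 5′ part (0.287 for the plus strand without replicate 2) and 0.119 for the upper flank (0.0288 without replicate 2).

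**Figure D3:**
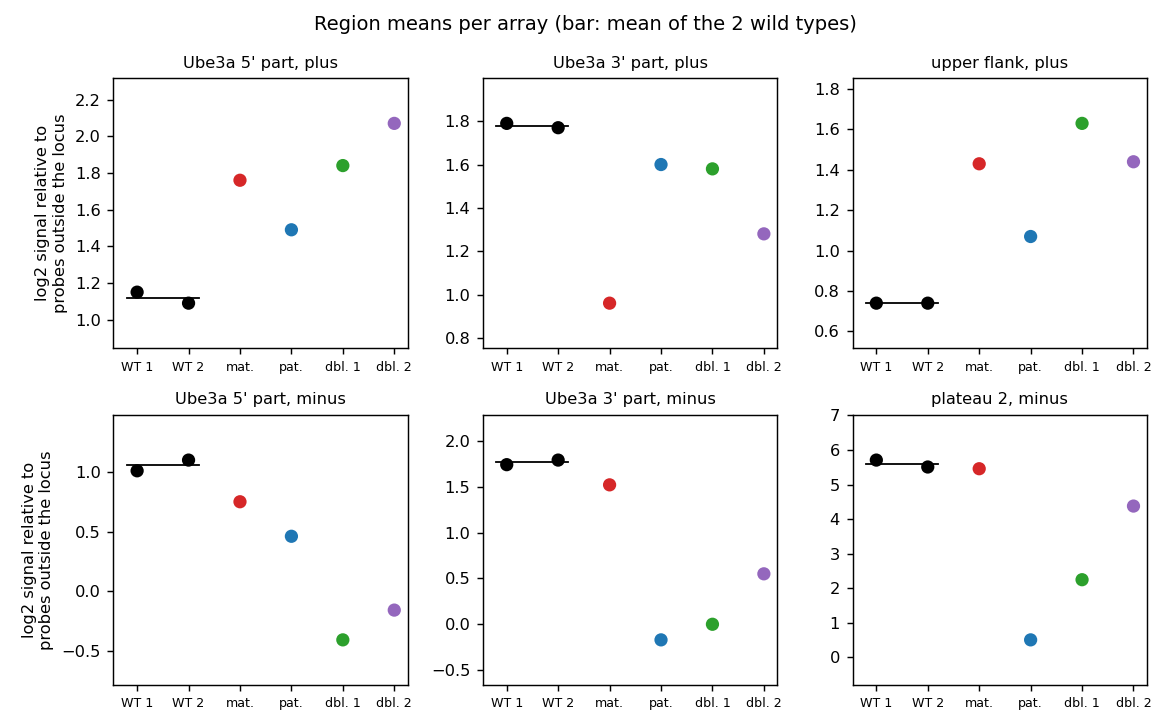
Mean log2 signal of 6 regions, relative to probes outside the locus, with 1 point per total RNA array and a bar at the mean of the 2 wild types (WT), for the maternal (mat.), paternal (pat.) and double (dbl.) deletions; vertical axes do not start at 0. The plus strand of the Ube3a 3′ part runs from 0.96 in the maternal deletion to 1.79 in wild-type replicate 1, and plateau 2 of the minus strand from 0.51 to 5.71.

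PolyA RNA was compared with total RNA of the same wild-type samples to ask how much of each strand is polyadenylated. Minus-strand plateau 2 was depleted from polyA RNA: relative to each array's own 75th percentile it fell by 2.52, with differences of -2.51 and -2.53 in the 2 pairs. On catalogue probes alone it fell by 0.75, the smallest decrease over the settings tried. Plateau 4, with the other high wild-type level, fell by 0.83 (-0.81 and -0.85 in the pairs) and plateau 5, at the Snrpn end, by 0.25 (-0.27 and -0.23). Plus-strand RNA of the 3′ part of Ube3a was 1 higher in polyA RNA (0.98 and 1.02 in the pairs), the same as the plus strand of the lower flank (65890585 to 66383531), at 1, and close to its minus strand, at 0.96. The signs of these 3 values turn on the scale of probes outside the locus, where they are -0.26, -0.27 and -0.30, while plateaus 2, 4 and 5 are at -3.78, -2.09 and -1.51. Plateau 2 was thus lower in polyA RNA than the Ube3a 3′ part by more than the spread of the pairs. Either scale shifts all regions of an array alike, so this gap cannot differ between the scales. On the polyA arrays the 75th percentile outside the locus was low, at intensities of 44 and 43.5 over a background of 34. The minus strand opposite the 3′ part was 0.28 higher in polyA RNA on the planned scale (0.37 and 0.19 in the pairs). On the outside-locus scale it was at -0.98. Opposite the 5′ part the minus strand was at 0.85 and -0.41, in the same order. With the replicate number as a block in limma, adjusted p was 2.04e-06 for plateau 2, 2.09e-05 for plateau 4 and 0.00215 for plateau 5. It was 1.23e-05 for the plus strand of the 3′ part and 0.00694 opposite it. Plateau 5 turned to 0.39 when scaled on probes well above background, and plateau 4 then missed the threshold at -0.19 (adjusted p = 0.0708 in limma without the block).

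**Figure D4:**
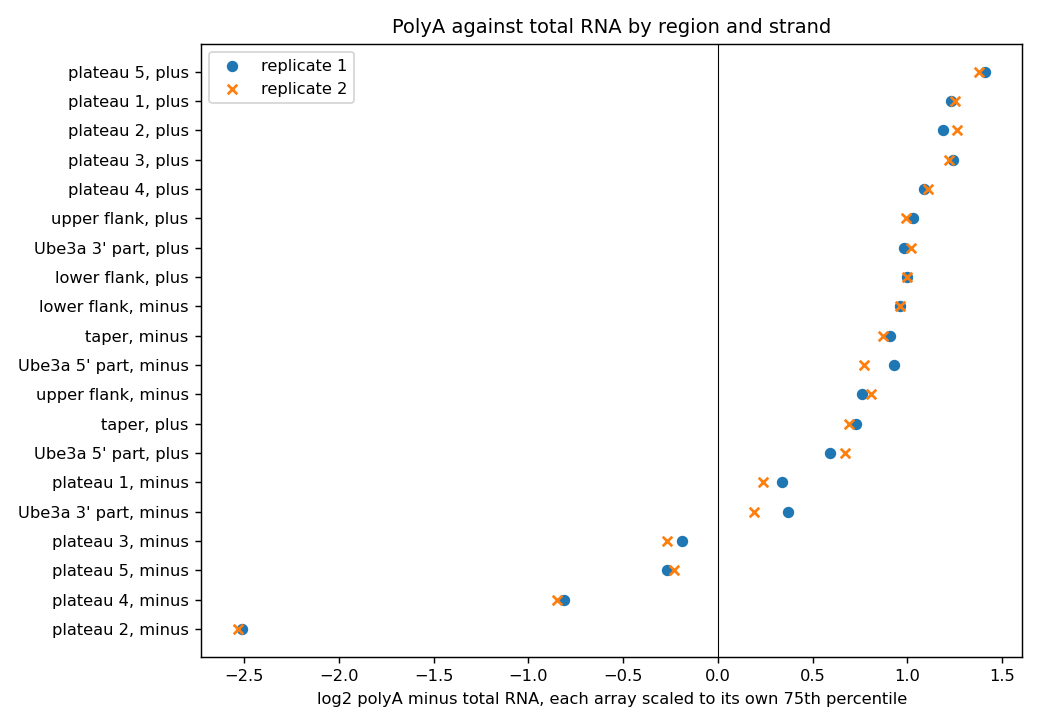
Log2 difference of polyA minus total RNA, each array scaled to its own 75th percentile, for 10 regions on both strands, with a circle for pair 1 and a cross for pair 2. Minus-strand plateau 2 lies lowest, at -2.51 and -2.53, and the plus strand of the Ube3a 3′ part at 0.98 and 1.02.

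Counts over the whole array followed the planned scale and groups, and depended on both. For the maternal deletion, limma called 574 of 49384 probes (548 higher, 26 lower) and 0 of 356 bins, with 14 bins under an unadjusted p of 0.05. The probe count was 22 without wild-type replicate 1, 21 without replicate 2, and 6293 and 6201 without double-deletion replicates 1 and 2. The bin count was 0 without either wild type (4 and 5 bins at an unadjusted p under 0.05) and 101 (56 higher, 45 lower) without either double-deletion replicate. On the outside-locus scale 0 probes were called, with 6184 under an unadjusted p of 0.05. For the paternal deletion it called 37986 probes (32924 higher, 5062 lower) and 338 bins (290 higher, 48 lower). The planned scale adds 1.12 to this change, and how many of the calls come from that was not isolated. With the outside-locus scale and separate double-deletion samples, 8929 probes were called and 22% were higher in place of 86.7%, and with that scale and the planned groups 0 were called, with 9177 under an unadjusted p of 0.05. Leaving out wild-type replicate 1 or 2 gave 4348 or 4425 probes and 37 or 40 bins. Most probes and bins called for the paternal deletion without a wild type were lower, whereas most were higher with all samples. For the double deletion, 10648 probes (45.6% higher) and 41 bins (36.6% higher) were called. On the outside-locus scale these were 4444 probes (61.5% higher) and 69 bins (75.4% higher). On the planned scale, most called probes and bins were higher when either double-deletion replicate was left out. They were mostly lower when either wild type was left out. Without wild-type replicate 1 or 2 there were 5148 or 5334 probes, and without double-deletion replicate 1 or 2 there were 17077 or 35761 probes and 208 or 335 bins.

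Between the double and the maternal deletion, 3878 probes (244 higher, 3634 lower) and 0 bins were called, with 54 bins under an unadjusted p of 0.05. Leaving out either wild type gave 2115 probes and 29 bins, and leaving out double-deletion replicate 1 or 2 gave 11327 or 32216 probes and 178 or 343 bins. The direction turned with the replicate left out: without double-deletion replicate 2 most called probes and bins were higher. Without replicate 1 most called bins were higher and most called probes lower. Between polyA and total RNA, 38909 of 43871 probes (78.4% higher) and 341 bins (83.9% higher) were called. On the outside-locus scale these were 31878 probes (38.8% higher) and 222 bins (10.8% higher).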

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

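The tests of explanations in this part, and the test of the difference between the maternal and the paternal deletion, were chosen only after the results were seen.

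The sample with the deletion on the maternal chromosome differed from the sample with it on the paternal chromosome by a limma test of the difference itself on the outside-locus scale, which sets 1 sample against 1 and takes the spread from the wild-type pair. The log2 difference, maternal minus paternal deletion, was 4.95 for minus-strand plateau 2 (adjusted p = 2.07e-05), 3.77 for plateau 4, 2.81 for plateau 5, 1.80 for plateau 3, 1.66 for plateau 1, 1.69 opposite the 3′ part of Ube3a and 0.29 opposite the 5′ part. On the plus strand it was -0.64 for the 3′ part (adjusted p = 0.000686), 0.26 for the 5′ part, 0.36 for the upper flank (adjusted p = 0.00452), 0.23 opposite plateau 2 and -0.30 opposite plateau 1. With the double deletions pooled, none of these passed: the lowest adjusted p was 0.0919 (plateaus 1, 3 and 4 and opposite the 3′ part), with 0.0985 for plateau 2 and the plus strand of the 3′ part and 0.142 for the upper flank. A difference between parents of origin and a difference between these 2 samples cannot be told apart.

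The green channel, in which no labelled sample was hybridized, held spots well above background: 19 for the maternal deletion, 21 for wild-type total RNA replicate 1, 5 for replicate 2, and 4 and 14 for double-deletion replicates 1 and 2. A count of 0 allows up to 3, and the paternal deletion and both polyA arrays had 0. No explanation was tested.

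Plus-strand signal beyond the upper change point was higher than wild type on all 4 deletion arrays. The minus strand of the same flank was at most 0.06 higher, which argues against minus-strand RNA read on the wrong strand, and the highest difference on the plus strand of the lower flank was -0.01, which argues against array scale. The gain fell with distance from the change point, with a Spearman correlation over 55 bins of -0.57 in the maternal deletion, -0.70 in the paternal deletion, and -0.76 and -0.77 in the double-deletion replicates, and bins of 1 array are not independent. Ube3a transcription that runs on across the joined ends of the deletion may explain this and stays open, since no bound was set before these correlations were seen, and so does a change in another transcript that starts beyond the change point, which was not tested.

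Double-deletion replicate 2 kept more minus-strand signal than replicate 1, by 2.13 in plateau 2, where the wild types differed by -0.19 (replicate 2 minus 1). Array scale is argued against, as the minus strand of the lower flank differed by 0.01. For wild-type RNA mixed into replicate 2, 2 of 20 combinations of region and strand lay outside the range from replicate 1 to wild type by more than 0.19. They were the plus strand of the 5′ part (replicate 2 minus 1: 0.23) and of the 3′ part (-0.30). This range takes replicate 1 as the unmixed state of replicate 2. The 2 samples carry different promoter deletions, and the 0.19 comes from the wild-type pair, so the test cannot decide and this mixing stays open. Maternal-deletion RNA mixed in stays open for the same reason, with 1 of 20 combinations outside its range, again the plus strand of the 5′ part. The minus strand of the upper flank lay outside that range by 0.18, just under the 0.19. A limit of 2 combinations was set after the values were seen, so these counts do not set the 2 kinds of mixing apart. The different promoter deletions of the 2 samples also stay open, and the 2.13 could be their effect. Each was measured on 1 sample, and titles and genotype labels disagree on which is which.

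Minus-strand signal below the lower change point persisted in the paternal deletion, at 0.46 opposite the 5′ part of Ube3a. Background or cross-hybridization on these probes is argued against, as the paternal deletion lay 0.62 above the nearer double-deletion replicate on the same probes. The minus-strand change from wild type stepped by -1.24 at the change point, towards the deleted side. A transcript from beyond the deletion that runs on across the joined ends may account for the signal and stays open, as does minus-strand RNA from the intact maternal chromosome, since this step was seen before the test was chosen and does not set them apart.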

How the results depend on the processing

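The settings with the double deletions pooled for regions (for probes and bins this grouping was planned), the outside-locus scale with separate double-deletion samples, catalogue probes alone, and moderation over the regions alone were chosen after the data were seen. The others were planned.

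The arrays limit the results as follows. Single deletions have no replicate, the spread rests on 1 wild-type pair, and all deletions share those wild types, although on the plus strand single wild types gave the same change points. Of the probes opposite the 3′ part of Ube3a, 51.8% were well above background in the paternal deletion, so its depletion there depends on the offset, and 61.4% and 56.6% of spots were on the polyA arrays. Not run: slide and scan as batches (1 of each), and alternatives that need annotated genes (gene lists, their correlation, exons and introns). No group has the 3 samples that other splits or an outlier test need.

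For regions between genotypes, of 660 combinations of change and setting, apart from pooling and leaving out a replicate, 618 kept direction and side of the threshold in limma, 19 lost the call, 5 gained it and 18 turned. Minus-strand plateau 2 was lower in the paternal deletion (-6.27 to -2.79) and the double deletion (-3.36 to -1.23) under every setting, and opposite the 3′ part of Ube3a the minus strand was lower too (-4.32 to -0.67 and -2.50 to -0.67). The 3′ part was lower on the plus strand in the maternal deletion (-1.20 to -0.68), and the upper flank higher in the maternal (0.51 to 1.97), paternal (0.26 to 1.60) and double deletion (0.68 to 2.08). Pooling the double deletions left each value as it was and ended the call in 31 of 44 combinations. The difference between the 2 samples then counts as spread, and the prior degrees of freedom also went from 2.9 to 1. Which of them ended each call was not tested. For the maternal deletion the 3′ part had -0.82 on the plus strand (adjusted p = 0.0811) and -0.24 on the minus strand (0.88), and the upper flank 0.70 (0.0811). For the paternal deletion the plus strand of the 3′ part had -0.18 (0.455), plateau 2 had -5.10 (0.0615) and the upper flank 0.33 (0.126). For the double deletion the plus strand of the 3′ part had -0.35 (0.13) and plateau 2 had -2.29 (0.135). Against the maternal deletion it had 0.47 (0.18) and -1.24 (0.18) on the plus and minus strands of the 3′ part, and -2.14 (0.284) in plateau 2.

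Other scalings turned several changes. For the paternal deletion, the plus strand of the 3′ part was 0.94 on the fixed scale, 0.17 with the median, 1.09 with probes above background and 0.42 with quantile normalization (adjusted p 1.31e-45 to 0.455 over all settings). Opposite the 5′ part it was 0.52 on the fixed scale and 0.67 with probes above background, and the plus strand of plateau 2 was 0.85, 0.07, 1 and 0.18 in the order of the first list. For the double deletion, the plus strand of the 3′ part was 0.03 on the fixed scale, 0.46 with probes above background and -0.07 with quantiles (adjusted p = 0.0783, range 4.12e-16 to 0.627). On the fixed scale and with probes above background, the plus strand of plateau 1 was 0.18 and 0.62, against -0.20 on the outside-locus scale. The minus strand of the taper between Ube3a and the lower flank was 0.11 and 0.55, against -0.26. That of the upper flank was 0.18 and 0.62, against -0.19. The upper flank of the double against the maternal deletion became a call, at 0.46 (fixed scale), 0.31 (median), 0.77 (probes above background) and 0.32 (quantiles). The maternal deletion's -0.24 opposite the 3′ part was -0.10 with probes above background as the scale, -0.18 on those probes alone and -0.24 with all 8 samples (adjusted p 2.95e-09 to 0.88), and its plateau 2 became a call at -0.29 with the median (6.55e-06 to 0.911). Its plateau 1 lost the call at -0.05 (probes above background as the scale), -0.17 (those probes alone), -0.19 (all 8 samples) and -0.20 (median over probes), with adjusted p from 3.63e-07 to 0.88, and its plateau 3 at -0.14 (probes above background as the scale). In the maternal deletion the strand opposite the 3′ part also lost its call under the settings named for it. Leaving out 1 replicate kept 171 of 176 combinations. Without double-deletion replicate 1 the minus strand of the upper flank turned to 0.06, from -0.45 without replicate 2, and the upper flank of the double against the maternal deletion ranged from 0 to 0.20. The plus strand of plateau 1 in the double deletion lost its call without replicate 1 (adjusted p = 0.0668) and without replicate 2 (0.0648), and that of the 5′ part against the maternal deletion without replicate 2. The cause was not tested.

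For polyA RNA, of 128 combinations 98 kept direction and call, 6 lost the call and 24 turned, and all 32 with a replicate left out were kept. Apart from the replicate block itself, these calls and the adjusted p-values below are from fits without the block. Such p-values of the main fit are not meaningful for single regions, so the values matter more here than the calls. Plateau 2 ranged from -3.78 to -0.75. Plateau 4 was -0.19 with probes above background as the scale (adjusted p = 0.0708, range 3.57e-33 to 0.0708), and plateau 5 was 0.39 there, -0.25 with all 8 samples and -0.14 on catalogue probes (4.71e-13 to 0.354). With the median, the series matrix and the outside-locus scale, the plus strand of the 3′ part was -0.18, -0.44 and -0.26, that of the lower flank -0.18, -0.21 and -0.27, and its minus strand -0.22, -0.22 and -0.30. The plus strand of the 5′ part, at 0.63 on the planned scale, turned in sign under several settings. It was -0.75 background-subtracted, -0.42 with processed signal, -0.55 with the median, -0.36 with quantiles, -1.11 in the series matrix and -0.63 on the outside-locus scale. The strand opposite the 3′ part, at 0.28 on the planned scale, was in that order -0.79, -0.47, -0.90, -0.40, -1.61 and -0.98. It was also -0.21 with offset 10 and -0.17 as a median over probes. These lists hold only settings in which the sign turned. The replicate block (paired samples) changed no call.

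Counts moved most. For the maternal deletion, 574 probes became 945 without background correction, 3794 background-subtracted, 3557 with processed signal, 1902 with offset 10, 1058 scaled on probes above background, 1650 without the filter, 1133 in the series matrix, 149 with all 8 samples, 982 on catalogue probes and 4335 with the outside-locus scale and separate samples. limma called 0 with the median (5000 at an unadjusted p under 0.05), the outside-locus scale (6184), quantiles (3789) and probes above background on all arrays (2046). Leaving out 1 replicate gave 21 (wild-type replicate 2) to 6293 (double-deletion replicate 1). For the paternal deletion, 37986 became 11935 background-subtracted, 11033 processed, 16057 with offset 10, 3082 with the median, 15655 on catalogue probes, 8929 with the outside-locus scale and separate samples, and 0 with the outside-locus scale (9177 unadjusted), quantiles (17189 unadjusted) and the series matrix (3427 unadjusted), with 4348 (without wild-type replicate 1) to 48052 (without double-deletion replicate 1). For the double deletion, 10648 became 5944 with the median, 20284 scaled on probes above background, 4444 on the outside-locus scale, 0 with quantiles (15459 unadjusted), 6960 on probes above background, 3138 in the series matrix, 17056 with the outside-locus scale and separate samples and 4342 on catalogue probes (5148 without wild-type replicate 1 to 35761 without double-deletion replicate 2). Against the maternal deletion, 3878 became 92 without correction, 51 background-subtracted, 108 processed, 90 with offset 10, 577 scaled on probes above background, 1820 with all 8 samples, 8840 with the outside-locus scale and separate samples, 1360 on catalogue probes, and 0 with the median (8079 unadjusted), the outside-locus scale (6728), quantiles (7930), probes above background (6505) and the series matrix (2363), with 2115 (without either wild type) to 32216 (without double-deletion replicate 2). For polyA RNA, 38909 became 24870 background-subtracted, 25439 processed, 23463 with quantiles, 25568 on probes above background, 10016 in the series matrix and 14417 on catalogue probes, the last 3 on fewer probes.

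In bins, the maternal deletion's 0 (14 unadjusted in limma) became 45 background-subtracted, 40 processed, 4 with offset 10, 58 in the series matrix, 83 with the outside-locus scale and separate samples and 16 on catalogue probes (0 without wild-type replicate 1 or 2, with 4 and 5 unadjusted, to 101 without either double-deletion replicate). The paternal deletion's 338 became 58 with the median, 82 with quantiles, 135 with the outside-locus scale and separate samples and 0 on the outside-locus scale (93 unadjusted) and in the series matrix (85 unadjusted), with 37 (without wild-type replicate 1) to 353 (without either double-deletion replicate). The double deletion's 41 became 106 without correction, 116 background-subtracted, 115 processed, 112 with offset 10, 250 scaled on probes above background, 69 on the outside-locus scale, 88 with quantiles, 68 in the series matrix, 110 with all 8 samples, 108 as medians over probes, 202 with the outside-locus scale and separate samples and 94 on catalogue probes (40 without wild-type replicate 1 to 335 without double-deletion replicate 2). Against the maternal deletion, 0 (54 unadjusted) became 54 background-subtracted, 54 processed, 47 with offset 10, 97 with the outside-locus scale and separate samples and 25 on catalogue probes (29 without either wild type to 343 without double-deletion replicate 2). The polyA count of 341 became 222 on the outside-locus scale. The cause was not tested. The scale shift was measured but not isolated as a cause, and some settings tested fewer probes.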

Other observations

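No explanation was tested in this part, and its values were picked after the data were seen, on the outside-locus scale.

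On the plus strand opposite minus-strand plateau 1, just past the Ube3a block, the maternal deletion fell by 0.39 (adjusted p = 0.0156, 0.0811 with the double deletions pooled, limma), and the paternal deletion differed by -0.09. The minus strand of the upper flank fell by 0.45 in double-deletion replicate 1 and differed by 0.06 in replicate 2.

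Across bins in wild type, the strands were correlated in the lower flank (r = 0.87, 50 bins) and less so in the span from Ube3a to Snrpn (r = 0.29, 53 bins), where bins of 1 profile are not independent replicates. In the lower flank 9 bins lay above 3 on the plus strand, and 5 of them did so on both strands. In the span from Ube3a to Snrpn 4 bins lay above 3 on the plus strand, and all 4 did so on the minus strand. Minus-strand plateaus 2, 4 and 5 of this span had means above 3 themselves, so the 4 bins do not show a link between the strands. The bin from 66650001 to 66660000 had 4.71 on the plus and 7.90 on the minus strand, that from 66750001 to 66760000 had 3.1 and 6.17, that from 66940001 to 66950000 had 4.89 and 5.54, and that from 67050001 to 67060000 had 3.48 and 6.20. In the paternal deletion the minus strand of these bins differed from wild type by -0.41, -2.43, -1.50 and -1.25, in the same order.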
